A study of Fragaria vesca with 9 samples.

How the data were processed

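Stranded mRNA libraries of axillary buds were sequenced as 150 bp paired reads, per the labels' protocols, from plants grown in 16 h days and 8 h nights at 22 °C and 18 °C under 250 µmol m−2 s−1. The labels place each of the 9 libraries in one of 3 genotypes (H4, FT3OE and RdV, 3 libraries each). The genotype label of the FT3OE libraries names the Hawaii-4 background, and their titles name FT3; the codes US4, in the titles of H4, and UB4, in those of FT3OE and RdV, are not defined by the labels, and no fit can separate them from H4.

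The authors deposited expected counts per gene and TPM per gene for 34006 genes. The expected counts, which are estimates and not normalized, held whole numbers in 97.5% of values and were rounded here before testing. TPM, deposited by the authors, are scaled to a fixed sum per library after division by effective gene length. STAR, RSEM and edgeR are named in the submitters' processing notes, without versions or roles; the genome build and annotation are not given in the sources used here. Reads shared between near-identical copies were divided by the authors' estimation, so single members of such families are uncertain. In all, 10465 genes had 0 counts in each library.

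The deposited identifiers do not match the gene table used here (0 of 34006 matched), so the 29 gene lists fixed in advance could not be tested, because no table pairs identifiers with names. The same holds for the alternatives planned for those lists. The genes named in the text follow a rule. It takes the 2 higher and 2 lower identifiers with the largest absolute log2 fold change in each comparison and in the set shared by both comparisons with H4, among genes with adjusted p under 0.05, a mean of at least 5 CPM and no overlap between the libraries of the groups. It adds 5 identifiers whose names were recalled from the strawberry literature. The comparisons, tests, alternatives, gene lists and this rule were set before the data were examined.

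Genes were filtered with filterByExpr, which left 18587, scaled with TMM, and tested with the quasi-likelihood functions glmQLFit and glmQLFTest of edgeR 4.0.16 in R 4.3.3, with all 9 libraries in one fit. p-values were adjusted by the Benjamini-Hochberg method, and genes with adjusted p under 0.05 are called. The 3 comparisons were FT3OE with H4, RdV with H4 and RdV with FT3OE, of which the last also tests whether the effects against H4 differ. CPM use TMM-scaled library sizes. Ratios of summed counts have exact 95% binomial intervals, and a group at 0 was given a floor of 3 counts over its summed total. Principal components used log2 CPM with a prior count of 2. Calls per linkage group were tested with Fisher's exact test, and runs of calls in windows of 20 neighbouring tested genes were set against 1000 shuffles within linkage groups, with Python 3.11.15 and scipy 1.17.1.

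Totals ranged from 23110936 to 44916866 counts, a ratio of 1.94, and the 2 deepest libraries were both FT3OE. A floor of 3 counts is 0.1298 CPM in the shallowest library and 0.0668 in the deepest. On simulated data with the real means and library sizes and 200 changed genes among 18587, the edgeR test recovered 52.2%, 82.1% and 92.4% of genes changed 1.5-fold, 2-fold and 4-fold for FT3OE against H4, and 71.6%, 73.1% and 92.4% for RdV against H4. For RdV against FT3OE it recovered 61.2%, 77.6% and 98.5%. Unchanged genes made up 6.8%, 5.4% and 8.1% of the calls in the 3 comparisons. The real data gave far more calls than 200, which makes the Benjamini-Hochberg cutoff less strict than in the simulation. The simulation also gave all groups the same dispersion per gene, though RdV libraries varied more. These rates therefore need not hold for the real tests.

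Alternatives were RLE scaling, library totals alone, DESeq2 1.42.0, limma 3.58.1 on log2 TPM with pseudocounts of 1 and 0.1 and with a minimum mean of 1 TPM, no filter, a filter of 1 CPM in 3 libraries, robust dispersions, fits of only the 6 libraries compared, the replicate number as a block, a log2 threshold of 1, an adjusted p under 0.01, and leaving out each library in turn. Equal depth by thinning to 23110936 counts, a correction for the trend of each library with effective gene length, and other count minimums for genes read on one side only, and fold changes on log2(CPM + 0.5) against separate H4 libraries, were added after the data had been seen.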

Results

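The data were 9 RNA-seq libraries from axillary buds of woodland strawberry, *Fragaria vesca*, taken undifferentiated from node 4 of plants with 4 leaves. An axillary bud forms at the base of a leaf and can become a runner, which spreads the plant, or a branch crown, a short shoot that can carry an inflorescence. The series addresses how the fate of these buds is set and how they grow out into branch crowns. There were 3 genotypes with 3 libraries each: H4, the Hawaii-4 accession; FT3OE, a line in the Hawaii-4 background whose name is read here as FT3 overexpression; and RdV, a separate ecotype. Total expected counts in replicates 1, 2 and 3 were 30448627, 23110936 and 29464475 in H4, 26493202, 44045170 and 44916866 in FT3OE, and 30507161, 27027190 and 26797546 in RdV. The sample titles carry the code US4 in H4 and UB4 in FT3OE and RdV, and the labels do not define either code. If they mark a difference in the buds or their handling, it runs with every comparison against H4 and cannot be told apart from genotype, whereas FT3OE and RdV share one code. The labels do not say that the replicates came from separate plants, so the p-values measure the spread between these samples, which may be technical.

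The genotypes separated from one another more than the replicates did. Values of log2(CPM + 1) correlated across genes at r = 0.9939 to 0.9985 within the 9 pairs of one genotype and at 0.9818 to 0.9936 between genotypes. Genes are not independent replicates in these values. Every pair of one genotype differed by more than counting noise, with chi-square per degree of freedom of at least 5.97, so no library was counted as a duplicate. By this measure RdV replicate 2 stood furthest from its group, at 31.77 with RdV replicate 1 and 22.07 with RdV replicate 3. The other pairs of one genotype reached at most 10.55, and pairs of different genotypes were at least 34.11. The first principal component of log2 CPM carried 58.7% of the variance and placed H4 at −48.32 to −46.76, FT3OE at −20.92 to −14.66 and RdV at 59.73 to 71.79. The second carried 19.2% and set FT3OE, at −37.99 to −37.14, apart from H4 at 26.34 to 29.95, with RdV at 7.49 to 14.31. The third, with 6.5%, separated RdV replicate 1, at −29.56, from RdV replicate 2, at 33.79.

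**Figure D1:**
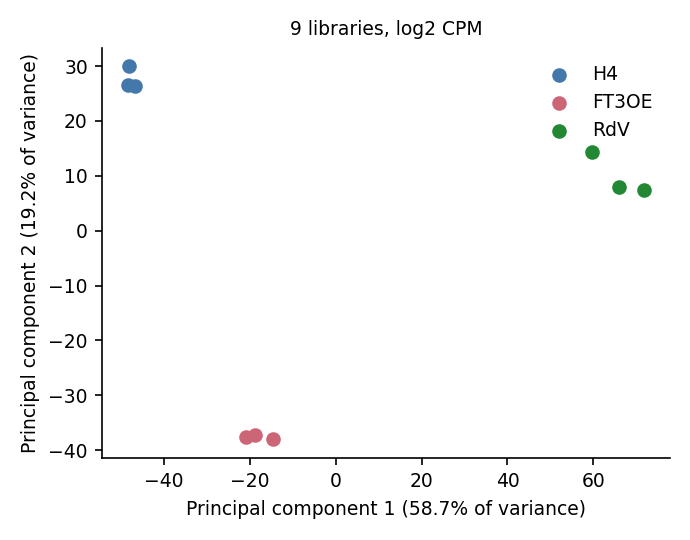
Scores of the 9 libraries on the first and second principal components of log2 CPM, which carried 58.7% and 19.2% of the variance, with one point per library coloured by genotype. The 3 libraries of each genotype lie together, FT3OE lies between H4 and RdV on the first component, and FT3OE lies apart at −37.99 to −37.14 on the second.

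Of 18587 genes tested, 5884 differed between FT3OE and H4, 8936 between RdV and H4, and 4122 between RdV and FT3OE (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The deposited tables hold gene identifiers without names, so named families and pathways are not described here. Genes are given by identifier, and 5 identifiers carry names recalled from the strawberry literature, which the files do not pair with them. The digit before the g in an identifier is taken, by the naming convention of the Hawaii-4 gene models, as the linkage group, and the number after it as the order along that group; no annotation was used.

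The comparison of FT3OE with H4 asks what changes in the bud when FT3, a member of the family of the flowering signal FLOWERING LOCUS T, is overexpressed. The targeted gene separated the groups first. FvH4_3g09870, recalled as FveFT3, had 7584, 11460 and 13889 counts in FT3OE replicates 1, 2 and 3, against 3, 1 and 0 in H4 and 1, 0 and 0 in RdV. Its mean was 278.3 ± 25.7 CPM (SD, n = 3) in FT3OE, and the summed counts, scaled for depth, stood in a ratio of 5550 to H4 (95% counting interval 2170 to 20400; the edgeR adjusted p was 2.75e-10). The H4 level rests on 4 counts: the fitted log2 change of 12.33 ran from 11.73 without H4 replicate 3 to 13.51 without H4 replicate 1. FvH4_7g12700, recalled as FveSOC1, a MADS-box regulator that promotes runner formation and represses flowering in strawberry, rose from 163.5 ± 7.1 CPM in H4 to 278.3 ± 4.3 in FT3OE (SD, n = 3 each), a log2 change of 0.77 ± 0.05 (SE) with an edgeR adjusted p of 2.92e-06.

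**Figure D2:**
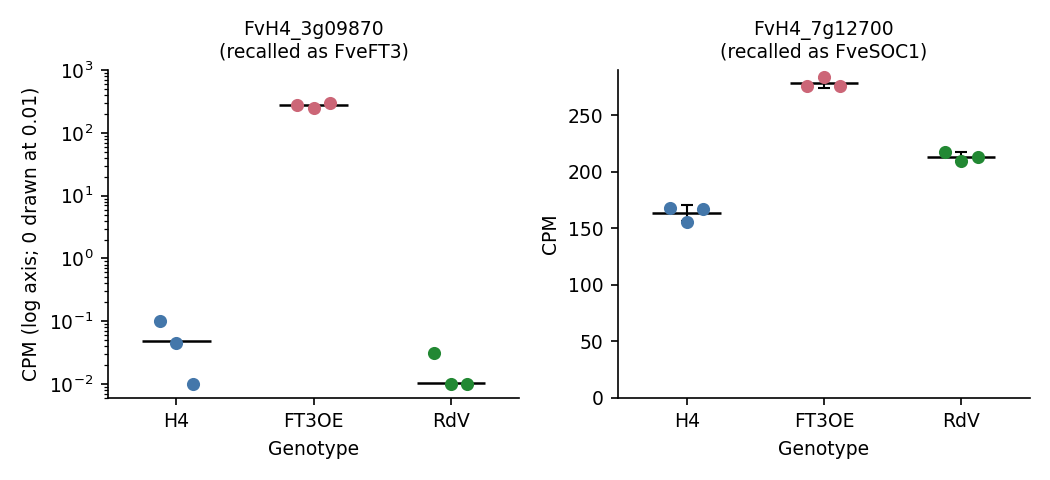
CPM of FvH4_3g09870 (recalled as FveFT3, log axis, with libraries at 0 drawn at 0.01) and FvH4_7g12700 (recalled as FveSOC1, linear axis) in the 3 genotypes. Points are libraries, horizontal lines are means over 3 libraries, and bars on the right panel are SD. FvH4_3g09870 averages 278.3 CPM in FT3OE against 0.049 in H4, and FvH4_7g12700 averages 163.5, 278.3 and 213.1 CPM in H4, FT3OE and RdV.

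The other recalled flowering genes had few or no counts in these buds. FvH4_6g00090, recalled as FveFT1, had 41 counts summed over FT3OE, 2 over H4 and 10 over RdV, too few to pass the low-count filter. The depth-scaled ratio of FT3OE to H4 was 13.8 (95% counting interval 3.59 to 118). FT3OE replicate 3 held 27 of the 41 counts and H4 replicate 3 both H4 counts. The ratio was 7.7 without FT3OE replicate 3, 8.69 without H4 replicate 1 and at least 5.96 without H4 replicate 3. Without the filter its log2 change in FT3OE was 3.58 ± 1.09 (SE) and did pass the threshold (edgeR adjusted p = 0.0317). FvH4_4g30710, recalled as FveFT2, had 0 counts in every library, which allows up to 0.0361 CPM in H4, 0.026 in FT3OE and 0.0356 in RdV for a floor of 3 counts per group. Intervals and floors cover counting error only. FvH4_6g18480, recalled as FveTFL1, a flowering repressor, had 15 counts in H4, 53 in FT3OE and 31 in RdV. Its TPM were 5.4, 2.13 and 2.12 in H4, 15.79, 5.59 and 7.8 in FT3OE and 6.35, 6.33 and 10.86 in RdV. TPM divide by effective gene length, so few counts alone do not show a low level. They do not show a high level either, since the TPM rest on 3 to 23 counts per library of this gene. Its log2 change in FT3OE was 1.34 ± 0.57 (SE; edgeR adjusted p = 0.0966) and in RdV 0.95 ± 0.60 (adjusted p = 0.215), neither past the threshold. For FvH4_6g18480 the values without H4 replicate 1 were 1.96 and 1.57, and without FT3OE replicate 1 the FT3OE value was 0.80. With limma on log2 TPM the FT3OE change did pass, with adjusted p of 0.0492, 0.0366 and 0.0251 under the 3 settings tried, while the RdV change passed in 2 of them, at 0.0458 and 0.0356.

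With FvH4_3g09870 included, 3112 genes were higher and 2772 lower in FT3OE than in H4. Most changes were small: the median absolute log2 change among the 5884 genes was 0.427, and 1003 changed at least 2-fold, 667 of them higher and 336 lower. After FvH4_3g09870, the identifier with the largest rise under the rule for named genes was FvH4_7g03990, from 2.19 ± 0.42 to 20.05 ± 1.86 CPM (SD, n = 3 each; log2 change 3.18 ± 0.13, SE, edgeR adjusted p = 1.82e-07). The largest fall was in FvH4_2g35050, from 226.1 ± 24.7 CPM in H4 to 2.25 ± 2.16 in FT3OE (log2 change −6.85 ± 0.39, edgeR adjusted p = 1.42e-06). FT3OE replicate 1 held 128 of its counts and the others 47 and 45, and without replicate 1 the log2 change of FvH4_2g35050 was −7.81. FvH4_4g19283 fell by 4.39 on the log2 scale, from 30.48 to 1.52 CPM. The calls were spread over the 7 linkage groups, with 30.3% to 32.8% of tested genes called on each and no group past the threshold (Fisher's exact test, 21 tests over the 3 comparisons, smallest adjusted p for this comparison 0.297). Higher calls were more frequent among long genes: of the 4647 longest tested genes 21.5% were higher and 11.3% lower, and of the 4647 shortest 11.1% were higher and 14.4% lower. The length correction removes this trend by construction. After it the rank correlation of length with log2 change across genes was −0.011, from 0.113, and 658 of the shortest genes were higher and 648 lower.

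The split of higher and lower calls depended on the scaling. Under library totals alone, 4568 genes were higher and 1777 lower in FT3OE than in H4 (72.0% higher, against 52.9% with TMM scaling), and under limma on log2(TPM + 1) 4078 were higher and 1291 lower (76.0%). With those settings the median log2 change of all tested genes was 0.107 and 0.128, against 0.013 with TMM. RLE scaling gave 50.8% higher and a median of 0.005. The limma fit also changed the test and the genes tested, so its shift cannot be put down to scaling alone.

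The comparison of RdV with H4 sets 2 ecotypes side by side, and it showed the most calls. In all, 4544 genes were higher and 4392 lower in RdV, and 2124 changed at least 2-fold, with 1375 higher and 749 lower. FvH4_7g12700 rose to 213.1 ± 3.9 CPM in RdV (SD, n = 3), a log2 change of 0.38 ± 0.05 (SE; edgeR adjusted p = 0.000112). Its log2 change in RdV against FT3OE was −0.39 ± 0.05 (SE; edgeR adjusted p = 0.000281), so that H4, RdV and FT3OE were in rising order.

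The largest RdV differences were genes read in one ecotype and not in the other. FvH4_3g23161 had 2041 counts over the 3 RdV libraries and 0 in the 6 others, at least 634-fold higher than H4 for a floor of 3 counts over the group. FvH4_3g15160 had 1325 counts in RdV and 0 in H4, at least 411-fold higher. In the other direction, FvH4_1g26750 had 0 counts in RdV and 2952 in H4, at least 1060-fold lower, and FvH4_4g24460 had 0 and 2446, at least 875-fold lower. With at least 10 counts in each library required on one side and 0 in each on the other, 30 genes were read in all 6 libraries of the Hawaii-4 background and in no RdV library, and 32 genes the other way round. With 3 libraries against 3, 41 genes were read in RdV and not in H4 and 32 in H4 and not in RdV, against 3 read in FT3OE and not in H4 and 1 in H4 and not in FT3OE. Requiring 50 counts left 16 and 15 genes in the comparison of RdV with the 6 other libraries.

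Calls between RdV and H4 took 46.0% to 51.3% of the tested genes of each linkage group. Linkage group 1, at 51.3% against 47.7% elsewhere, was the one past the threshold (Fisher's exact test, adjusted p = 0.0131). Long genes were again more often higher: of the 4647 longest 31.4% were higher and 17.6% lower, and of the 4647 shortest 17.9% and 25.3%. After the length correction, which removes the trend by construction, 1035 of the shortest were higher and 1013 lower. The densest run of calls in one direction lay at the end of linkage group 5. Among the last 20 tested genes there, from FvH4_5g39450 to FvH4_5g39750, 19 were higher in RdV than in H4 and 17 higher in RdV than in FT3OE, whereas in FT3OE against H4 4 were called. The top window of 20 neighbouring genes held 19 higher calls, and the highest count in 1000 shuffles of the calls within linkage groups was 16. The median log2 change of the block was 0.64 in RdV against H4 (25th to 75th percentile 0.40 to 0.84), a 1.55-fold difference, and −0.02 in FT3OE against H4. The 20 genes before it had a median of −0.09. This block was chosen after its values were seen.

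**Figure D3:**
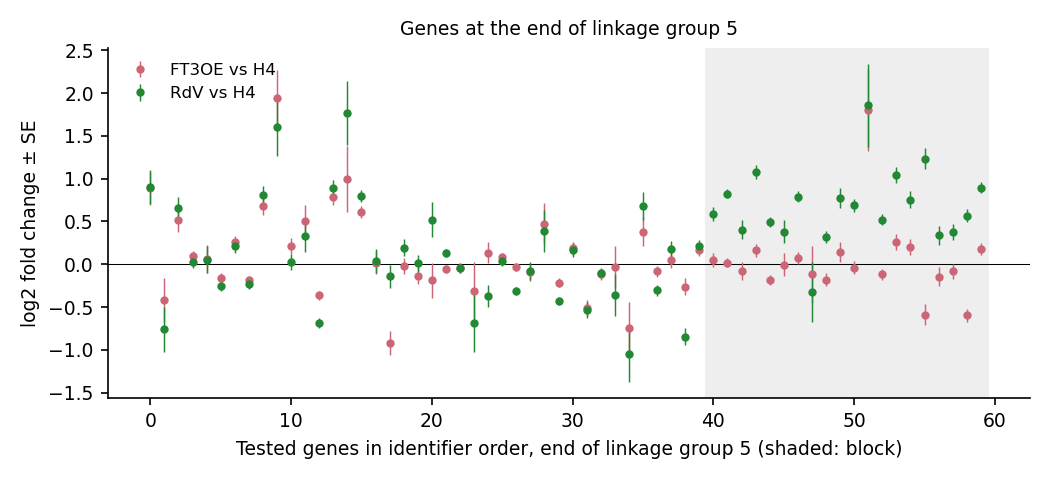
log2 fold changes against H4, with SE, of tested genes in identifier order at the end of linkage group 5, for FT3OE and RdV; the shaded part holds the last 20 tested genes. RdV has a median of 0.64 in the shaded part and −0.09 in the 20 genes before it, and FT3OE has a median of −0.02 in the shaded part.

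For this comparison too, the share of higher calls rose to 62.5% (5565 higher, 3341 lower) under library totals alone and 68.2% (5581 higher, 2599 lower) under limma on log2(TPM + 1), against 50.9% with TMM. The median log2 change of all tested genes was then 0.076 and 0.114, against −0.004. RLE scaling gave 50.5% higher and a median of −0.005. The limma fit again changed the test and the genes tested too.

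Most FT3OE calls were also RdV calls. Of the 5884 genes called in FT3OE, 4565 (77.6%) were called in the same direction in RdV, 2406 higher and 2159 lower, which is 51.1% of the RdV calls. Both percentages depend on the joint fit of all 9 libraries. Fits of only the 6 libraries compared gave 7291 FT3OE calls, 7953 RdV calls and 4784 shared, so the 2 shares were then closer. FvH4_7g03990 was 3.18 higher on the log2 scale in FT3OE and 3.43 higher in RdV, and FvH4_7g28670 2.92 and 3.29 higher. FvH4_1g03420 had log2 changes of −4.17 and −4.38, and FvH4_2g35050 of −6.85 and −4.09. Among the shared genes, 683 changed at least 2-fold in both comparisons, 480 higher and 203 lower. The median absolute log2 change of the shared genes was 0.443 in FT3OE and 0.555 in RdV.

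Both comparisons used the same H4 libraries, the ones titled US4, which by itself makes fold changes resemble each other. In 20 simulations of unchanged groups against shared controls no gene was called in both comparisons. With no gene changed, few calls can arise at all, so this does not measure how many shared calls the shared controls add. In these simulations the fold changes correlated across genes at r = 0.512, and 67% had the same sign. The observed values were r = 0.455, Spearman's rho = 0.703 and 78.7%. The observed covariance of log2 changes was 0.2674 and the simulated one 0.0237, a difference of 0.2437. Independent lists of these lengths would share 760.8 higher and 655 lower genes. A split of the 3 H4 libraries leaves 1 library on one side, so calls were not repeated on separate controls and part of the excess of calls may come from the shared ones. Without a test per gene, on log2(CPM + 0.5), the covariance was 0.1681 against the same 3 H4 libraries and 0.1546 to 0.162 over the 6 ways of giving FT3OE and RdV separate H4 libraries.

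**Figure D4:**
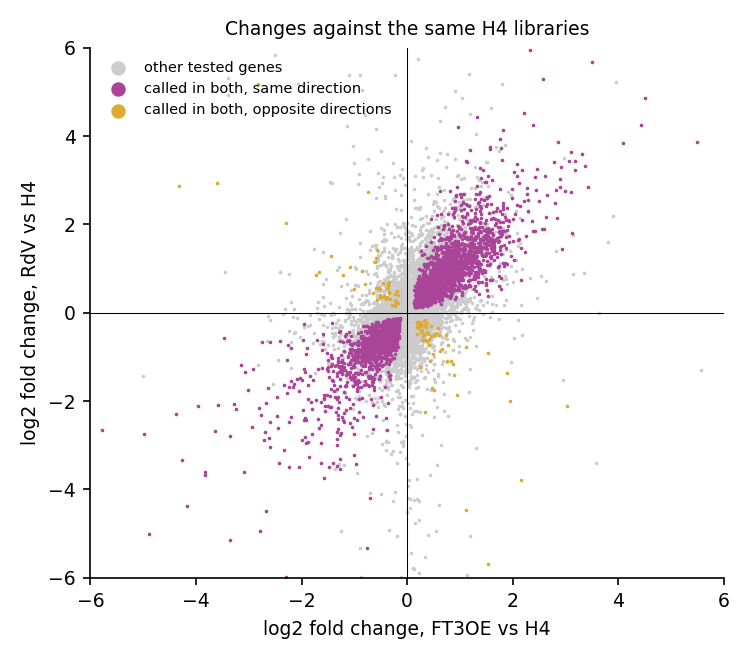
log2 fold change of each tested gene in FT3OE against H4 (x axis) and in RdV against H4 (y axis), with 116 genes outside the axis limits of −6 to 6 not drawn. Genes called in both comparisons number 4565 in the same direction and 109 in opposite directions.

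The comparison of RdV with FT3OE gave 2062 genes higher and 2060 lower in RdV, with 977 changed at least 2-fold (539 higher, 438 lower). FvH4_3g23161 and FvH4_3g15160 led the higher genes, and FvH4_3g09870 and FvH4_1g26750 the lower ones. FT3OE stood apart from both other genotypes in the same direction in 775 genes, 418 higher and 357 lower, and RdV did so in 3091 genes, 1591 higher and 1500 lower. Linkage group 2 held fewer calls than the rest (19.1% against 22.7%, Fisher's exact test, adjusted p = 0.000347) and linkage group 7 more (24.9% against 21.8%, adjusted p = 0.01). Fisher's test takes genes as independent, and calls of neighbouring genes were not, so the p-values for linkage groups are too small.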

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

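The tests of a displacement of H4, of gene length, of the end of linkage group 5 and of opposite neighbours were chosen after the results were seen; the tests of other splits and of reads lost in RdV were planned. Of the 4122 genes called between RdV and FT3OE, 109 were called in opposite directions against H4, 63 of them higher in FT3OE and lower in RdV. Opposite called changes against the same H4 libraries imply a difference between RdV and FT3OE, so for this set the test of RdV against FT3OE adds nothing. Independent lists would hold 1413 such genes.

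The edgeR test of RdV against FT3OE, which tests the difference itself, separated the following named genes. FvH4_3g09870, recalled as FveFT3, stood in a ratio of 23800 between FT3OE and RdV (95% counting interval 4270 to 941000). Its RdV side is 1 count in RdV replicate 1, without which it was at least 5000-fold higher in FT3OE for a floor of 3 counts over the group. FvH4_7g12700, recalled as FveSOC1, was lower in RdV than in FT3OE by a log2 value of −0.385. FvH4_2g35050 and FvH4_4g19283, which fell in both genotypes against H4, fell less in RdV, with log2 differences of 2.756 and 2.105; the first was 3.716 without FT3OE replicate 1. FvH4_3g23161 was at least 941-fold higher in RdV than in FT3OE, and FvH4_3g15160 stood in a ratio of 1830 (328 to 72400). The FT3OE side of FvH4_3g15160 is 1 count in FT3OE replicate 3, without which it was at least 374-fold higher in RdV. FvH4_1g26750 was at least 921-fold lower and FvH4_4g24460 at least 435-fold lower in RdV. FvH4_7g28670 rose more in RdV, by 0.37 on the log2 scale (edgeR adjusted p = 0.0433); its adjusted p lay between 0.0595 and 0.161 when any 1 library other than H4 replicate 2 or 3 was left out.

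The first pattern is the sharing of calls between FT3OE and RdV against H4. Of 100 regroupings of the 9 libraries into 3 groups of 3, only the real one gave as many shared calls, 4565 against 3250 for the highest other. Most regroupings mixed genotypes within groups, which widens the spread and leaves few calls. The test therefore shows that the libraries group by genotype, and cannot exclude chance as the source of the sharing. That highest regrouping kept the 3 H4 libraries together as controls and mixed FT3OE with RdV. It recovers genes in which both differ from H4, so it restates the shared calls and does not tell their cause. After the length correction 92.9% of the shared calls remained, which argues against gene length as the whole cause. A displacement of the H4 libraries alone, from handling, from genotype or from what the title codes US4 (H4) and UB4 (FT3OE and RdV) stand for, stays open. Of the FT3OE calls, 53.4% lay further from H4 in RdV than in FT3OE. That is more than the displacement alone predicted, and short of the 60% set as the bound against it after the results were seen. RdV also stood apart from both other genotypes in 3091 genes. Such changes can raise this share with or without a displacement of H4, so the share cannot decide. Of the FT3OE calls 961 had a called difference further from H4 in RdV, against 775 the other way. Among the 4565 shared genes 68.9% lay further in RdV, which are the same 3144 genes set over a smaller total. The shared genes were chosen for calls in RdV too. The codes cannot be told apart from genotype, since they run with it. A shared bud state in FT3OE and RdV is the biological hypothesis, untested here beyond these counts.

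The second pattern is the block at the end of linkage group 5 that was higher in RdV. A scaling factor moves all genes of a library together, and the 20 genes before the block had a median of −0.09 in RdV against H4. This argues against scaling as the source. The median log2 change of the block against H4 was 0.636 with TMM, 0.717 with library totals and 0.803 with TPM. Another factor per library could hardly have removed the block, so these 3 values add little. The median relative to H4 was 0.688, 0.502 and 0.777 in RdV replicates 1, 2 and 3, and between −0.035 and 0.009 in FT3OE. Extra copies of the segment in RdV are a candidate explanation, since the 1.55-fold median begins abruptly and runs to the last tested gene. One copy ratio would give a narrow spread of folds, but 31.4% of 924 other windows, laid end to end, had a smaller spread. Of these windows 1 had a higher median, 0.695, and among overlapping windows the highest was 0.984, on linkage group 4, where FT3OE was higher too; in RdV against FT3OE the block had the highest median, 0.63. Copies and shared regulation therefore cannot be told apart without DNA.

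The third pattern is the set of genes read on one side only between RdV and the Hawaii-4 background. Loss of RdV reads at absent or diverged genes would add to the genes missing from RdV. The ratio of the 30 genes missing from RdV to the 32 read only in RdV was 0.94 (95% exact binomial interval 0.55 to 1.59), so no excess was seen. The genes read only in RdV do not show why the 30 were missing, so the ratio cannot exclude this loss for them. Genes that lost only part of their reads were not counted. The 32 genes have models yet gave no reads in the Hawaii-4 libraries. Reads passing between neighbouring gene models would give neighbours changed at least 8-fold in opposite directions; there were 7 such pairs against a mean of 2.37 in 1000 shuffles, whose 99th percentile was also 7, so this stays open for a few pairs. A difference between the ecotypes in promoters or gene copies is the biological hypothesis. The ratio above bears only on an excess of genes missing from RdV, and promoters and gene copies were not tested directly.

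The 3 counts of called genes were set against the 10 splits of each set of 6 libraries into 3 and 3. These are too few for a share under 0.05; the real split (1 of 10) gave 5884, 8936 and 4122 calls for FT3OE against H4, RdV against H4 and RdV against FT3OE, and the highest other split gave 0 in each.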

How the results depend on the processing

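Equal depth, length correction and the other count minimums were chosen after the data had been seen. The counts of calls stayed within 1.5 times under every alternative except stricter thresholds, but membership moved more: 70.7% to 71.6% of the shared calls were also shared under the limma fits on TPM and 82.5% under library totals. With an absolute log2 change of at least 1 they were 1003 for FT3OE against H4, 2124 for RdV against H4, 977 for RdV against FT3OE and 683 shared. With adjusted p under 0.01 they were 3270, 2281 for RdV against FT3OE and 2508 shared, by construction of the threshold. Leaving out each library in turn gave 4119 to 7372 calls for FT3OE against H4, 7499 to 10014 for RdV against H4, 2883 to 5183 for RdV against FT3OE and 3303 to 5690 shared, each highest without RdV replicate 2. That library enters FT3OE against H4 only through the joint fit. A fit of only the H4 and FT3OE libraries gave 7291 calls. The log2 change of FvH4_3g09870 in FT3OE ran from 11.73 to 13.51. Differences between RdV and FT3OE that were not called changed sign without FT3OE replicate 1: left-out libraries gave log2 differences of −0.689 to 0.149 for FvH4_6g18480 and −0.622 to 0.013 for FvH4_1g03420; the cause was not tested. The replicate numbers did not pair the libraries throughout: deviations of same-numbered libraries correlated at −0.178 to 0.181, with 2 of 9 over 0.1. A library matched its own number best in 7 of 18 cases. Between H4 and RdV the same-numbered values were 0.04, 0.181 and 0.165, and those with FT3OE ran from −0.178 to 0.042. A batch shared by H4 and RdV is therefore not ruled out. With the replicate number as a block, 5312, 8533 and 3611 genes were called and 4169 shared. Among named genes it ended the call of FvH4_7g28670 between RdV and FT3OE, though the log2 difference stayed at 0.375. The limma fits on log2 TPM ended that call too, with limma adjusted p of 0.0894, 0.169 and 0.0607. The length correction kept 5576 of 5884 FT3OE calls and 8334 of 8936 RdV calls against H4. Depth limits what can be said of genes near the floor, such as FvH4_6g00090 and FvH4_4g30710.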

Other observations

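The tests in this part were chosen after the result was seen, except the test for a block of genes near an insertion in FT3OE. A second region held genes higher than in H4 in both FT3OE and RdV. The window of 20 tested genes with the highest median log2 change in FT3OE against H4 ran from FvH4_4g29350 to FvH4_4g29630 on linkage group 4. Its median was 1.06 in FT3OE and 0.98 in RdV, with 11 and 10 of its genes called higher and 0 lower. Between RdV and FT3OE 4 of its genes were called higher and 3 lower, so its members did not all change by the same amount in both. In 1000 shuffles of the FT3OE fold changes within linkage groups, the highest window median was at most 0.898.

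Neighbouring genes changed together more often than by chance of position. Adjacent tested genes called in the same direction numbered 1080 in FT3OE against H4, where 1000 shuffles within linkage groups gave a mean of 934.3 and at most 1039. In RdV against H4 there were 2440 such pairs (mean 2149.0, at most 2294), and in RdV against FT3OE 672 (mean 458.8, at most 517). Among genes changed at least 8-fold between RdV and H4, 27 adjacent pairs moved in the same direction, against a mean of 2.42 and at most 9 in shuffles. Tandem copies that share reads would add to such pairs, and this was not tested.

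A hypothesis was that the FT3OE line differs from H4 in a block of neighbouring genes, as a chromosomal change near an insertion or a carried-over segment would give. The densest window held 12 genes of one direction among 20, from FvH4_1g15090 to FvH4_1g15500. The 99th percentile of 1000 shuffles was 13, and 148 of the shuffles held a window as high. The planned test therefore found no dense block of calls in one direction. It counts calls and not their size, and it could not detect a short block or one of mixed directions, so such blocks stay open. The window on linkage group 4 with a median of 1.06 had a median of 0.98 in RdV and −0.004 between RdV and FT3OE, so its rise over H4 was not particular to the FT3OE line. That likeness to RdV does not exclude a carried-over segment in the FT3OE line, so the hypothesis stays open for this window.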
